A study of Mus musculus with 6 samples.

How the data were processed

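The 6 libraries were made from poly-A selected RNA (500 ng for each library preparation) of laser-microdissected lumbar ganglion neurons, and per the labels' protocols they were barcoded, mixed and run on 3 lanes, so the lanes do not separate the groups. Batches of surgery, dissection, RNA extraction or library preparation were not given in the sources used here. Groups were taken from the labels: 3 sham and 3 crush. The library preparation was not stated to keep strand, so genes that overlap on opposite strands cannot be told apart by their reads. Nothing analysed here gives the number of neurons, the number of animals per library or the total of mapped fragments.

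Expression was given as FPKM per isoform and per library in the authors' deposited table, with an interval and a status for each value. Per the submitters' processing notes the tools were TopHat 1.3.2, Cufflinks 1.1.0 and Cuffdiff 1.2.1, with genome build mm9. The same deposited table holds the authors' comparison of the groups, with a p-value and a q-value per isoform and a log2 fold change, from the authors' pooled group estimates. The authors' exon file gives the coordinates of the transcripts and was used for positions, lengths and strands only. The table holds 60744 isoforms, of which 46299 were assembled and 14445 carry a reference identifier, under 17022 gene names, 1682 of them unnamed loci. A status other than OK in at least 1 library was found for 4461 isoforms in 885 genes. The exon file holds 109956 transcripts, and the 49212 without values, 33939 of them of 1 exon, were not used here. A reference genome of another build was at hand and was not used, so that builds were not mixed.

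The suffix that numbers the isoforms of a gene was removed from the names, and FPKM was summed over the isoforms that share a gene name. For 16 genes these isoforms lie on 2 or more chromosomes. Total FPKM per library was 320947, 364606 and 321152 in sham 1 to 3 and 322293, 316263 and 338365 in crush 1 to 3, and the 10 most abundant genes held 4.30% to 5.52% of it. These totals are not depths. FPKM keeps no count of reads, so the depth is unknown and no counting interval was computed; the deposited intervals for isoforms of 1 to 10 FPKM had like widths in all 6 libraries.

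Genes and isoforms with a mean of at least 1 FPKM over the 6 samples were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model with moderated variance and a mean-variance trend, 2-sided), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Differences between isoforms of a gene were tested with limma's diffSplice (F test) over genes with at least 2 tested isoforms. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation. They were also tested with fry, which asks whether the genes of a list move, on balance, one way, and in its mixed form whether they change in either direction; neither form compares a list with other genes. Of 39 lists, 37 had at least 3 members tested, 751 genes in all; the lymphocyte list had 1 and the muscle and fat list 0. Camera called 21 of the 37 lists, 14 upwards and 7 downwards. With an estimated correlation camera called 0, with 7 at an unadjusted p under 0.05 and adjusted p from 0.0696 to 0.991. Fry called 7, namely regeneration (adjusted p = 0.00618), potassium channels (0.0392), myelinated neurons (0.0135), sensory transcription factors (0.0155), injury transcription factors (0.00691), interleukin-6 signalling (0.0187) and macrophages (0.00115), and its mixed form called 27. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

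The tests, their design, the gene lists and the rule for genes to be named were fixed before the data were examined. Named are the 10 genes of largest rise and the 10 of largest fall among called genes whose groups do not overlap; from each list the 2 called members that rose and the 2 that fell with the smallest adjusted p, or the member of smallest adjusted p where none passed; Atf3, Sox11, Gap43, Sprr1a, Gal, Npy, Jun and Stat3 always; the 5 isoforms of largest rise and of largest fall; and the 5 genes of smallest adjusted p in the isoform-difference test. The most abundant members of the cell type lists were added to these, by abundance alone. Some of these members are not reported here. The Gal, Gap43 and Pvalb isoforms quoted from the authors' deposited table are isoforms of named genes and were chosen after their values were seen.

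Each test was tested on simulated data drawn around the real means, in 10 sets with 200 changed features each. The noise was drawn independently for each gene or isoform, with the same spread in every library. The real libraries were unequal (sample weights 0.162 for sham 2 and 2.86 for crush 1), so the simulated rates need not hold for them. The gene test over 12289 genes recovered 51.6%, 95.8% and 99.8% of genes changed by 0.5, 1 and 2 on the log2 scale, and 4.13% of its calls were unchanged genes. The isoform test over 24485 isoforms recovered 0.299%, 32.4% and 79.5%, with 4.03% of calls unchanged. The isoform-difference test over 6746 genes recovered 2.39%, 34.3% and 83.0%; 24.6% of its calls were unchanged genes, and it called a mean of 7.3 genes where none had changed. In the 1 simulated set for lists, camera called 0 lists in error, but in the real samples it called 7 to 19 lists under each of the 9 other splits into 3 and 3, against 21 for sham and crush.

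Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, and a mean of at least 5 FPKM), each library left out in turn, the replicate number as a block, upper-quartile and quantile scaling, no variance trend, sample weights, adjusted p under 0.1, reference isoforms only, the Simes form of diffSplice and the authors' q under 0.01. Chosen after seeing the data were a restriction to values of status OK, the omission of both sham 2 and crush 3, removal of the trend on transcript length (loess span 0.5) and, for the lists, quantile scaling.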

Results

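RNA was measured from neurons cut by laser microdissection out of dorsal root ganglia, the clusters beside the spinal cord that hold the cell bodies of sensory neurons. The ganglia came from lumbar levels 3, 4 and 5 of male C57Bl/6 mice, labelled adult and 4 to 6 weeks old, on the operated side, 7 days after surgery. In 1 group the sciatic nerve, which carries axons of neurons in these ganglia, had been crushed for 10 seconds. In the other it had only been exposed for 10 seconds (sham surgery). Each group had 3 polyadenylated-RNA libraries, called sham 1 to 3 and crush 1 to 3 here. Nothing in the sources used here states that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The values were FPKM, fragments per transcript scaled by the authors for transcript length and mapped fragments, so the depth of each library was unknown. The deposited interval of an isoform of 1 to 10 FPKM had a median half-width of 31.3% to 32.5% of its value in the 6 libraries. Between 12087 and 12347 genes reached 1 FPKM in a library. Over the 12289 genes tested, sham 1 and sham 3 correlated at r = 0.996, whereas sham 2 correlated with them at 0.978 and 0.981. The 3 crush libraries correlated with each other at 0.993 to 0.996. These are correlations across genes, which are not independent replicates.

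The first comparison asked which genes differed between the crush and sham libraries. Nothing analysed here tells which of the captured neurons had an axon in the crushed nerve. On the log2(FPKM + 1) scale used for all rankings here, neuropeptide Y (Npy), a peptide transmitter, had the largest rise, from 22.0 ± 6.14 to 219 ± 50.6 FPKM (SD, n = 3 in each group, as for all values below), a ratio of means of 9.94 (log2 change 3.27, adjusted p = 0.00509). Sprr1a, a cornified-envelope protein known to be made by injured sensory neurons, rose from 90.5 ± 19.0 to 513 ± 110.4 FPKM, a ratio of 5.67 (log2 change 2.49, adjusted p = 0.00509). Atf3, a transcription factor of the stress response to axon injury, rose from 50.5 ± 14.3 to 171 ± 21.8 FPKM (log2 change 1.77, adjusted p = 0.0106), and the neuropeptide galanin (Gal) from 63.4 ± 19.9 to 231 ± 57.2 FPKM (1.86, adjusted p = 0.0147). Gap43, a growth-cone protein, rose from 276 ± 36.5 to 521 ± 73.6 FPKM (0.91, adjusted p = 0.0220). Stat3, a transcription factor of cytokine signalling, did not pass, at 109.6 ± 1.80 in sham and 123 ± 1.91 FPKM in crush (0.17, adjusted p = 0.221). Jun and Sox11, also fixed in advance as injury genes, were not analysed here. In the mm9 genome build, Npy lies on chromosome 6 from 49772210 to 49779485 and Sprr1a on chromosome 3 from 92287903 to 92289943.

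Besides these, the genes of largest rise included 2 carbonic anhydrases, enzymes that interconvert carbon dioxide and bicarbonate. Car3 rose from 5.36 ± 0.145 to 38.9 ± 8.02 FPKM (log2 change 2.63, adjusted p = 0.00450) and Car1 from 1.32 ± 0.217 to 6.98 ± 1.71 FPKM (1.76). The calcium-dependent membrane-binding protein Anxa10 rose from 0.438 ± 0.102 to 5.13 ± 2.56 FPKM (2.02, and 3.19 with a pseudocount of 0.1). Lmo7, a LIM-domain protein of cell junctions, rose from 4.16 ± 1.03 to 18.6 ± 3.23 FPKM (1.93), and the lipase-family gene Lipn from 0.792 ± 0.0651 to 5.75 ± 1.45 FPKM (1.89). The cholecystokinin B receptor (Cckbr) rose from 3.75 ± 0.401 to 14.4 ± 1.40 FPKM (1.70). The largest falls included 2 calcium-binding proteins of sensory neuron subsets. Calretinin (Calb2) fell from 13.1 ± 3.19 to 3.80 ± 1.71 FPKM (log2 change -1.59, adjusted p = 0.0309), and parvalbumin (Pvalb), found in proprioceptive neurons, from 141 ± 22.3 to 51.9 ± 19.2 FPKM (-1.48, adjusted p = 0.0379). Pigz, an enzyme of glycosylphosphatidylinositol anchor synthesis, fell from 7.69 ± 0.664 to 2.06 ± 0.813 FPKM (-1.54), and the membrane protein gene Clec2l from 115 ± 8.39 to 54.1 ± 13.9 FPKM. The others of the 10 were the membrane protein gene Vstm2b (-1.31), the matrix link protein Hapln4 (-0.97) and the heparan sulfate sulfotransferase Hs3st2 (-0.94). Thrsp, a regulator of lipid synthesis (-0.93), Whrn, a scaffold protein of sensory cells (-0.93), and the transcription factor Onecut1 (5.42 ± 1.24 to 2.19 ± 0.516 FPKM) completed them. Exons of Pigz shared 96.2% of their bases with exons of its neighbour Ncbp2, and those of Pvalb shared 74.4% with exons of Ift27, so part of their values rests on how shared reads were divided.

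In all, 464 of 12289 genes passed, 293 higher and 171 lower after crush (limma, adjusted p under 0.05), and in each of them the 3 crush values lay all above or all below the 3 sham values. Such separation was found in 26.3% of all genes tested, against 10% by chance. Of the genes called, 64 rose by at least 1 on the log2 scale and 6 fell by at least that much; 6 called genes were unnamed loci. The number called depended on which libraries were tested, with fewer samples in each such test. It was 119 without sham 1, 1174 without sham 2, 75 without sham 3, 53 without crush 1, 82 without crush 2 and 99 without crush 3. With all 6 samples but only isoforms with a reference identifier summed, 67 of 8465 genes tested were called. Of the 59 genes taken by the naming rule that passed, 23, 59, 18, 17, 22 and 27 kept their call without sham 1, 2 and 3 and crush 1, 2 and 3. Npy, Car3, Sprr1a, Lmo7, Lipn, Car1, Cckbr, Flrt3, Nts, Chl1, Fst, Ctss and C1qc kept it under every alternative in which they were tested. The log2 change of 7 of the 59 moved by over 1.5 times under an alternative, and that of the others, such as Atf3 (1.56 to 1.97) and Nefh (-0.84 to -0.57), by less.

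**Figure D1:**
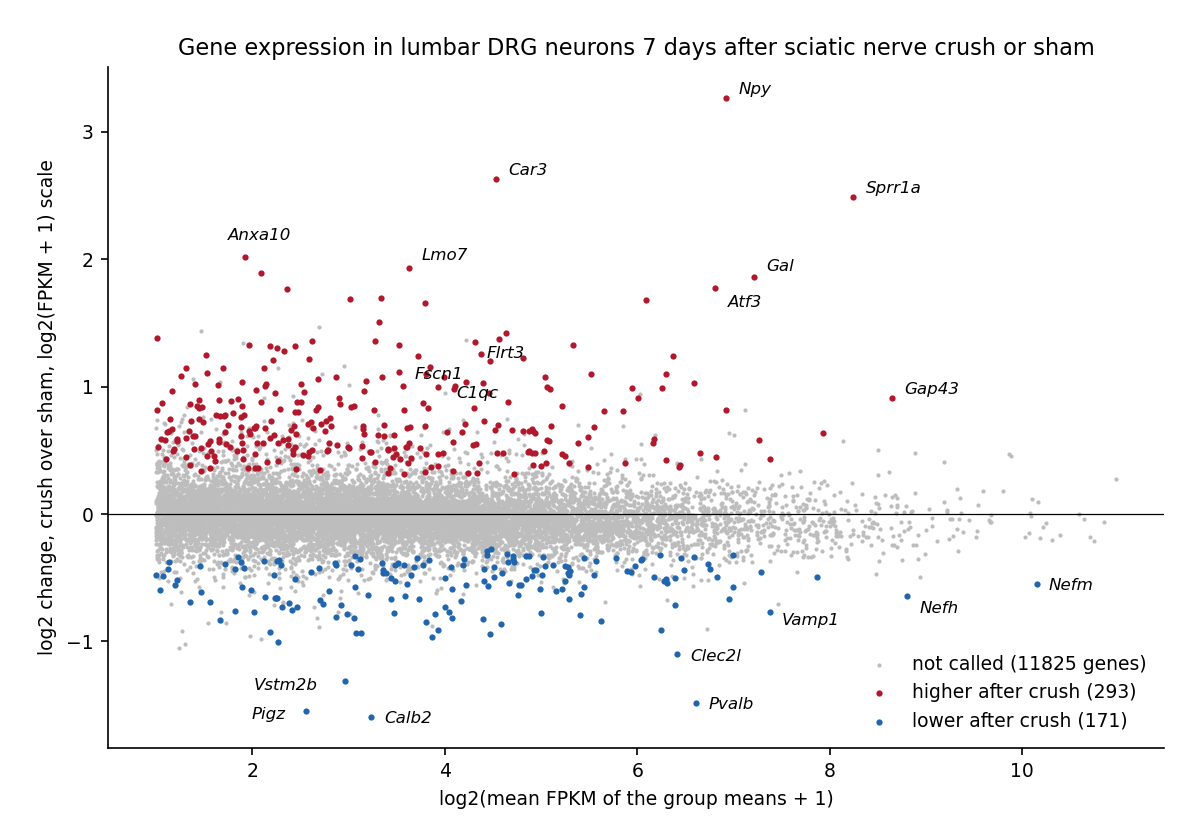
Each point is 1 of the 12289 genes tested, at its mean level (log2 of FPKM + 1, horizontal) and its log2 change of crush over sham (vertical), red where higher after crush (293), blue where lower (171) and grey where not called. Npy lies highest at 3.27 and Calb2 lowest among called genes at -1.59.

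**Figure D2:**
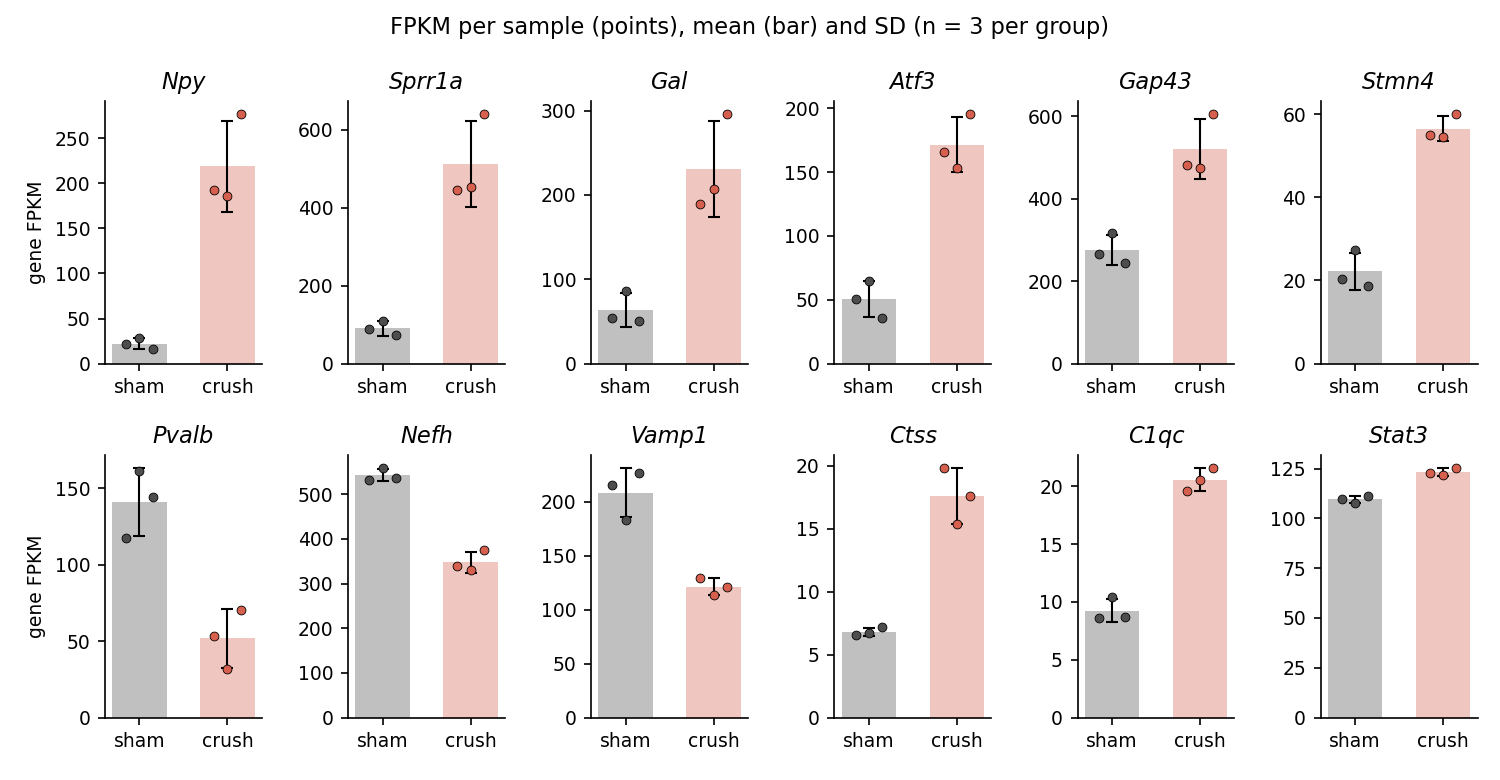
FPKM of 12 named genes in each sham (grey) and crush (red) library, with 1 point per library, bars for group means and lines for the SD (n = 3), each gene on its own axis from 0. The 3 crush values lie all above the sham values for Npy (mean 219 against 22.0 FPKM) and all below them for Nefh (347 against 543 FPKM); Stat3 is separated too but did not pass.

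Most genes of axon regeneration that were tested rose after crush. Of 36 members tested, 22 rose, 0 fell and 14 did not pass, with 29 rising when adjusted over the list alone. The median log2 change was 0.81. Flrt3, a membrane protein of cell adhesion and guidance, rose from 10.1 ± 0.785 to 27.5 ± 2.23 FPKM (log2 change 1.35, adjusted p = 0.00450), beside Cckbr, Atf3, Gal, Npy and Sprr1a above. Among 14 neuropeptides, 5 rose, 0 fell and 9 did not pass (6 rising when adjusted over the list alone; median 0.24). Neurotensin (Nts) rose from 31.5 ± 4.88 to 103 ± 13.4 FPKM (1.68). Among 21 transcription factors of axon injury, 4 rose, 0 fell and 17 did not pass (5 rising when adjusted over the list alone; median 0.23). Beside Atf3, the bone morphogenetic protein effector Smad1 rose from 19.2 ± 0.634 to 30.8 ± 1.59 FPKM (0.66, and 0.30 from reference isoforms alone). Interleukin-6 and JAK-STAT signalling had 1 member that rose, the transcription factor Stat5b (0.38, adjusted p = 0.0393), 0 that fell and 18 that did not pass (6 rising when adjusted over the list alone; median 0.21). Bone morphogenetic protein and transforming growth factor beta signalling had 3 that rose, 0 that fell and 21 that did not pass (3 rising and 1 falling when adjusted over the list alone; median 0.10). The activin-binding protein follistatin (Fst) rose from 2.80 ± 0.297 to 11.4 ± 2.56 FPKM (1.69).

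Against all other genes, these 5 lists passed camera with its preset correlation, upwards, with adjusted p of 2.05e-30 (regeneration), 0.0137 (neuropeptides), 1.35e-07 (transcription factors), 0.000435 (interleukin-6) and 0.0312 (bone morphogenetic protein). The adjusted p = 0.139, 0.583, 0.139, 0.229 and 0.374 with an estimated correlation, in the same order, so none of the 5 calls held with it. In sham 2 the neuropeptide list lay 0.31 above the other sham libraries (median log2 difference) and the regeneration list 0.15 above, while the bone morphogenetic protein list lay lower (-0.16). The rising regeneration genes numbered 16, 25, 12, 8, 11 and 11 without sham 1, 2 and 3 and crush 1, 2 and 3. The call of the bone morphogenetic protein list was lost without sham 2 (adjusted p = 0.212, median -0.03), crush 2 (0.0744) or both sham 2 and crush 3 (0.0704) and with upper-quartile (0.0815) or quantile scaling (0.0627). The range over its alternatives was 0.00707 to 0.374.

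Markers of large myelinated neurons, which sense touch and limb position, included several that fell after crush. Of 20 tested, 5 fell, 0 rose and 15 did not pass, with 11 falling when adjusted over the list alone. Among them 19 of the 20 had a negative log2 change and the median was -0.44. The heavy neurofilament gene Nefh fell from 543 ± 14.1 to 347 ± 23.4 FPKM (log2 change -0.64, adjusted p = 0.0147), and Whrn from 10.5 ± 1.14 to 5.02 ± 0.743 FPKM. Non-peptidergic nociceptor markers, of pain-sensing neurons that bind the lectin IB4, had 1 of 17 that fell, 0 that rose and 16 that did not pass (1 rising and 9 falling when adjusted over the list alone; median -0.25). The lysophosphatidic acid receptor Lpar3 fell from 31.0 ± 1.13 to 24.4 ± 0.580 FPKM (-0.33). Sensory neuron transcription factors had 1 of 15 that fell, 0 that rose and 14 that did not pass (1 rising and 7 falling when adjusted over the list alone; median -0.26). The POU-domain factor Pou4f3 fell from 11.1 ± 0.653 to 7.80 ± 0.187 FPKM (-0.46). In peptidergic nociceptor markers 0 of 13 passed in limma, also when adjusted over the list alone (median -0.07). The member with the smallest adjusted p was the membrane protein gene Tmem233, at 197 ± 17.7 and 161 ± 8.63 FPKM (adjusted p = 0.156). Pan-neuronal markers had 1 of 21 that fell, 0 that rose and 20 that did not pass (1 rising and 2 falling when adjusted over the list alone). The medium neurofilament gene Nefm fell from 1345 ± 35.5 to 923 ± 93.5 FPKM (-0.55, adjusted p = 0.0486). The list's median was -0.02, and 0.02 and 0.04 with upper-quartile and quantile scaling.

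Camera called the myelinated (adjusted p = 4.28e-08), non-peptidergic (0.000310) and transcription factor lists (0.00261) lower, and neither the peptidergic (0.601) nor the pan-neuronal list (0.727). The adjusted p = 0.159, 0.374, 0.174, 0.871 and 0.879 with an estimated correlation, in that order. The number of myelinated markers that fell was 0 without sham 1, sham 3, crush 1 or crush 2, 3 without crush 3 and 12 without sham 2, whose own values for this list lay lower than in the other sham libraries (median log2 difference -0.14). The list's median stayed between -0.50 and -0.34 and its camera call was kept without each of the 6 libraries (adjusted p = 5.86e-10 to 2.64e-06).

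Among ion channel genes, several potassium channels fell after crush. Of 37 potassium channel genes, 5 fell, 0 rose and 32 did not pass (13 falling when adjusted over the list alone; median -0.22). The modifier subunit Kcng4 fell from 5.71 ± 0.518 to 2.98 ± 0.0399 FPKM (log2 change -0.75, adjusted p = 0.00832) and the two-pore leak channel Kcnk1 from 39.3 ± 1.99 to 22.6 ± 2.55 FPKM (-0.78). Of 13 sodium channel genes, 1 fell, 0 rose and 12 did not pass (5 falling when adjusted over the list alone; median -0.14). The beta subunit Scn4b fell from 69.7 ± 2.09 to 50.6 ± 1.89 FPKM (-0.45, and -1.56 from reference isoforms alone). Of 17 calcium channel genes, 1 rose, 0 fell and 16 did not pass (1 rising and 1 falling when adjusted over the list alone). Cacna2d1, the alpha-2-delta subunit bound by gabapentin, rose from 49.4 ± 9.05 to 106 ± 4.44 FPKM, a ratio of 2.14 (adjusted p = 0.0123). The list's median and mean were 0.02, while camera's direction was down. Of 37 sensory transduction channels and receptors, 2 fell, 0 rose and 35 did not pass (3 rising and 5 falling when adjusted over the list alone; median -0.05). The 2 were the serotonin receptor Htr1d (-0.39) and the purine receptor P2ry1 (-0.46). Of 23 receptors for glutamate and gamma-aminobutyric acid, 1 fell, 0 rose and 22 did not pass (2 rising and 3 falling when adjusted over the list alone; median -0.09). The NMDA receptor subunit Grin1 fell from 31.5 ± 1.14 to 21.1 ± 1.18 FPKM (-0.56). Of 18 neurotrophic factor receptors, 2 rose, both co-receptors of the GDNF family, while 0 fell and 16 did not pass (2 rising and 3 falling when adjusted over the list alone; median 0.04). Gfra1 rose from 20.3 ± 4.41 to 43.5 ± 4.59 FPKM (1.08) and Gfra3 from 22.4 ± 0.428 to 35.8 ± 0.858 FPKM (0.65). All exon bases of Gfra1 also lie in exons listed under another name, GDNFR-alpha, and 63.3% in exons of Gm16277 on the opposite strand, so its own total is uncertain.

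In camera the potassium (adjusted p = 1.23e-06) and sodium channel lists (0.0138) passed downwards, and the calcium channel (0.984), sensory transduction (0.190), glutamate and gamma-aminobutyric acid receptor (0.312) and neurotrophic receptor lists (0.499) did not pass. The adjusted p = 0.229, 0.517, 0.991, 0.768, 0.871 and 0.670 with an estimated correlation, in that order. Falling potassium channel genes numbered 1, 17, 0, 0, 2 and 3 without sham 1, 2 and 3 and crush 1, 2 and 3. The sodium channel call was lost without sham 1 (adjusted p = 0.174) and crush 3 (0.0896; range over alternatives 0.000800 to 0.517). The sensory transduction list passed only without crush 2 (0.0172; range 0.0172 to 0.768), and the glutamate and gamma-aminobutyric acid list without sham 2 (0.00279; range 0.00279 to 0.953) or without both sham 2 and crush 3 (0.0247). In sham 2 the last list lay lower than in the other sham libraries (median -0.29).

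Among synaptic, cytoskeletal and guidance genes, members of several lists passed in either direction. Of 37 synaptic vesicle and release genes, 3 fell, 1 rose and 33 did not pass (10 falling and 1 rising when adjusted over the list alone; median -0.14). The vesicle fusion protein Vamp1 fell from a mean of 209 to 122 FPKM (log2 change -0.77 with a standard error of 0.103) and the calcium sensor Syt2 from 53.5 ± 1.81 to 38.3 ± 3.04 FPKM (-0.48). Syt4, another synaptotagmin, rose from 94.8 ± 7.53 to 129 ± 5.38 FPKM (0.45, and -0.03 from reference isoforms alone). Syt2 shared 79.2% of its exon bases with Ppp1r12b on the opposite strand, Vamp1 47.7% with Tapbpl and Grin1 51.5% with Anapc2. Since the library was not stated to keep strand, their values are uncertain. Of 32 neurofilament and microtubule genes, 3 rose, 2 fell and 27 did not pass (5 rising and 4 falling when adjusted over the list alone; median 0.01). The falls were Nefh and Nefm, and the rises included the stathmin Stmn4, a microtubule regulator (22.2 ± 4.51 to 56.5 ± 3.06 FPKM, 1.33), and the tubulin Tubb6 (0.73, and 1.17 with a pseudocount of 0.1). Tubb6 is uncertain for the same reason, sharing 36.5% of its exon bases with the more abundant Afg3l2 on the opposite strand. Of 33 actin cytoskeleton genes, 2 rose, 0 fell and 31 did not pass (6 rising when adjusted over the list alone; median 0.09). They were Gap43 and the actin-bundling protein Fscn1 (11.2 ± 0.616 to 28.3 ± 4.42 FPKM, 1.26). Of 37 guidance and adhesion genes, 6 rose, 1 fell and 30 did not pass (9 rising and 3 falling when adjusted over the list alone; median 0.07). Flrt3 and the adhesion molecule Chl1 rose, Chl1 from 15.9 ± 2.25 to 38.4 ± 3.72 FPKM (1.23), and Lingo1, a co-receptor for inhibitors of axon growth, fell (-0.31, adjusted p = 0.0429).

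Camera called the synaptic list lower (adjusted p = 0.000926) and the actin (0.00577) and guidance lists (0.0192) higher, and not the neurofilament and microtubule list (0.190). The adjusted p = 0.374, 0.624, 0.624 and 0.610 with an estimated correlation, in that order. Without sham 1 the synaptic (0.0529; range over alternatives 8.12e-05 to 0.374) and actin calls (0.0748; range 3.73e-05 to 0.624) were lost. The guidance call was lost without sham 2 (0.647, median -0.08), without both sham 2 and crush 3 (0.345) and with the length trend removed (0.180; range 0.00207 to 0.647). The neurofilament and microtubule list passed with quantile scaling (0.0278; range 0.0278 to 0.610). In sham 2 the actin list lay 0.28 above and the guidance list lay lower than in the other sham libraries (median -0.24).

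**Figure D3:**
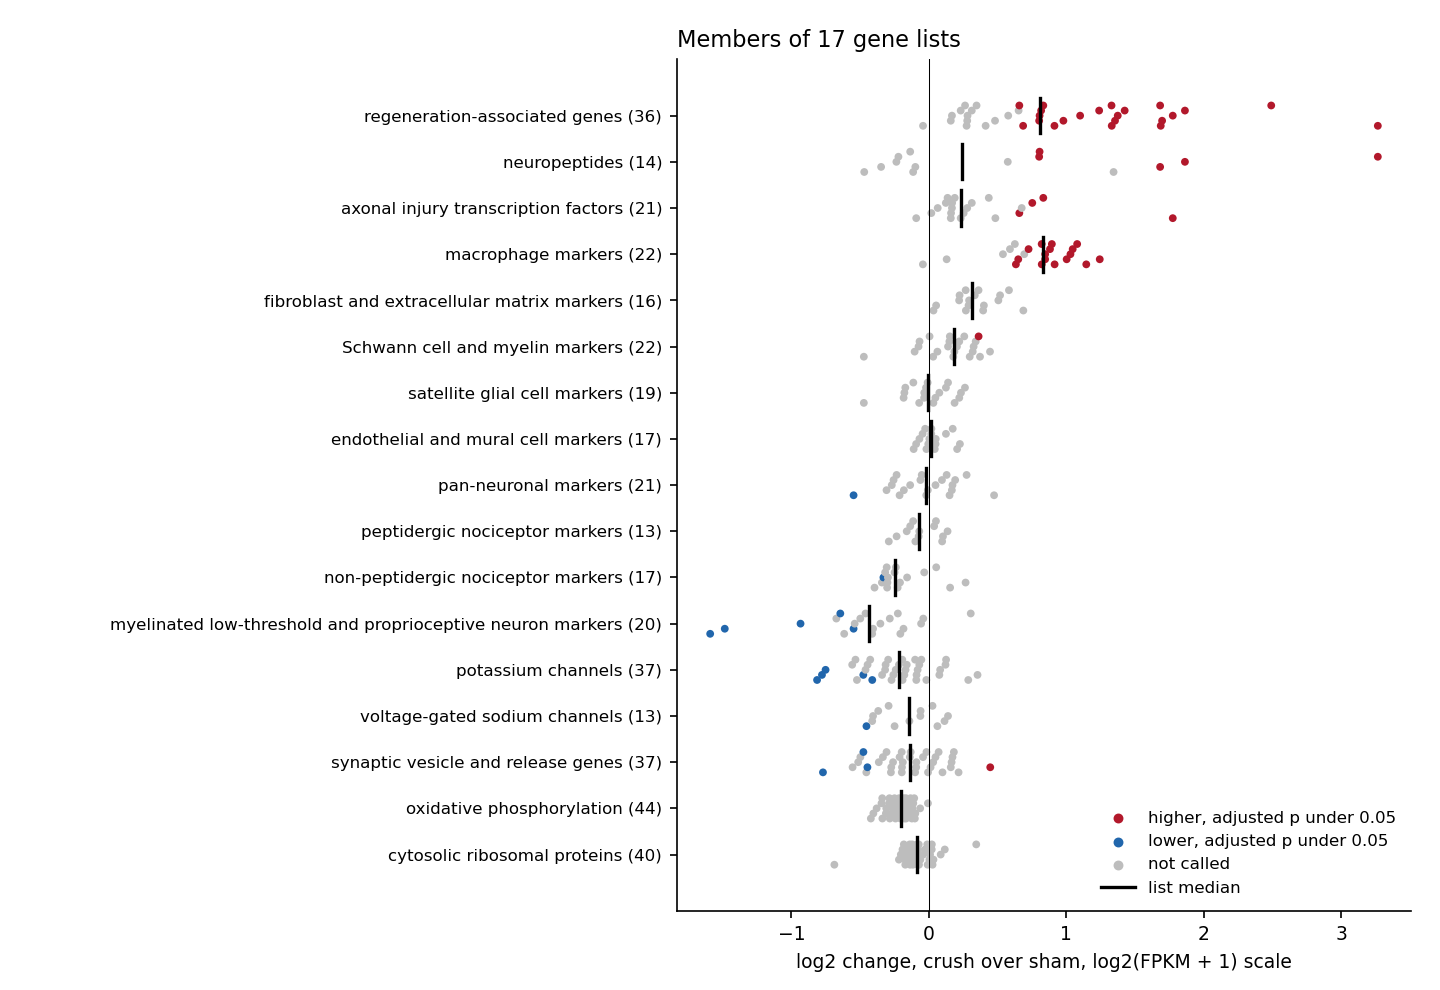
Log2 change of crush over sham for each tested member of the 17 lists shown (number of members in brackets), red where higher and blue where lower after crush, grey where not called, with the list median as a black line. The medians of the regeneration and macrophage lists are 0.81 and 0.83, and that of the myelinated neuron list is -0.44.

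Among markers of cells other than neurons, those of macrophages, the resident and invading phagocytes of the ganglion, rose after crush. Of 22 tested, 16 rose, 0 fell and 6 did not pass, with 20 rising when adjusted over the list alone and a median log2 change of 0.83. The lysosomal protease cathepsin S (Ctss) rose from 6.82 ± 0.305 to 17.6 ± 2.22 FPKM (log2 change 1.24, adjusted p = 0.00509) and the complement component C1qc from 9.23 ± 0.999 to 20.6 ± 0.996 FPKM (1.08, adjusted p = 0.00509). Of the abundant members, lysozyme (Lyz2) rose from 25.6 ± 2.01 to 46.9 ± 3.20 FPKM (0.85), whereas Cd74 (43.3 ± 8.91 and 69.9 ± 5.68 FPKM, adjusted p = 0.0521) did not pass. Of 22 Schwann cell and myelin markers, 1 rose, the fatty acid hydroxylase Fa2h (0.36), 0 fell and 21 did not pass (5 rising when adjusted over the list alone; median 0.18). The abundant S100b (-0.47) and Pmp22 (0.15) were among the 21. Satellite glia, which wrap each neuron, had 0 of 19 markers past limma, also when adjusted over the list alone. Their median was -0.01 while their mean and camera's direction were up, and the abundant Apoe stood at 1784 ± 469 in sham and 1545 ± 98.9 FPKM in crush. Fibroblast and matrix markers had 0 of 16 past limma, also when adjusted over the list alone, although all 16 were higher (median 0.31). The proteoglycan lumican (Lum) had the smallest adjusted p, 0.0961, and the most abundant, Apod, stood at 304 ± 93.9 and 417 ± 12.4 FPKM. In endothelial and mural markers 0 of 17 passed in limma, also when adjusted over the list alone (median 0.02), with Vwf at an adjusted p of 0.467 and the most abundant, Rgs5, at a log2 change of -0.05. Of 5 neutrophil markers, 1 rose, 0 fell and 4 did not pass (1 rising when adjusted over the list alone). Ly6g rose from 0.532 ± 0.178 to 2.42 ± 0.614 FPKM (1.15, and 2.0 with a pseudocount of 0.1), and the most abundant, S100a8, stood at 9.80 ± 5.58 and 4.80 ± 2.04 FPKM (adjusted p = 0.399). The list's median was -0.34 while its fry direction was up. Of the lymphocyte list 1 gene could be tested, Ccl5 (0.740 ± 0.380 and 1.44 ± 0.674 FPKM, adjusted p = 0.346), and of the muscle and fat list 0 reached 1 FPKM.

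The macrophage (adjusted p = 3.26e-23), Schwann cell (0.000315) and fibroblast lists (4.00e-06) passed camera upwards, and the satellite glial (0.725), endothelial (0.601) and neutrophil lists (0.737) did not. The adjusted p = 0.0696, 0.341, 0.374, 0.879, 0.879 and 0.879 with an estimated correlation, in that order, so none held with it. Macrophage markers that rose numbered 9, 20, 8, 7, 7 and 9 without sham 1, 2 and 3 and crush 1, 2 and 3, and in sham 2 this list lay 0.16 above the other sham libraries. Of the Schwann and satellite lists, 7 and 4 tested members stand in another list too.

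Genes of oxidative phosphorylation, the mitochondrial respiratory chain, included 0 of 44 that passed in limma, also when adjusted over the list alone. All 44 had negative log2 changes, with a median of -0.20, and the complex III subunit Uqcrc2, of smallest adjusted p (0.238), stood at 85.1 ± 0.289 in sham and 75.5 ± 3.75 FPKM in crush. Of 40 cytosolic ribosomal protein genes, 0 passed in limma, also when adjusted over the list alone (median -0.08). Rpl15 stood at 13.2 ± 1.67 and 17.1 ± 1.89 FPKM (adjusted p = 0.175) and shared nearly its whole exon sequence with Nkiras1 on the opposite strand. Camera called the oxidative phosphorylation list lower (adjusted p = 9.83e-06, and adjusted p = 0.670 with an estimated correlation) and did not call the ribosomal list (0.462 and, with an estimated correlation, 0.882). Both lists stood apart in sham 2, at 0.43 and 0.58 above the other sham libraries. Without sham 2 the oxidative phosphorylation median was -0.06 (adjusted p = 0.0469; range over alternatives 1.09e-07 to 0.670), and the ribosomal list turned upwards, with a median of 0.14 (adjusted p = 0.000266). Without both sham 2 and crush 3 it was upwards too (0.0123, median 0.06). It passed downwards without sham 1 (0.0232) and sham 3 (0.0193), and its range over alternatives was 0.000266 to 0.901.

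**Figure D4:**
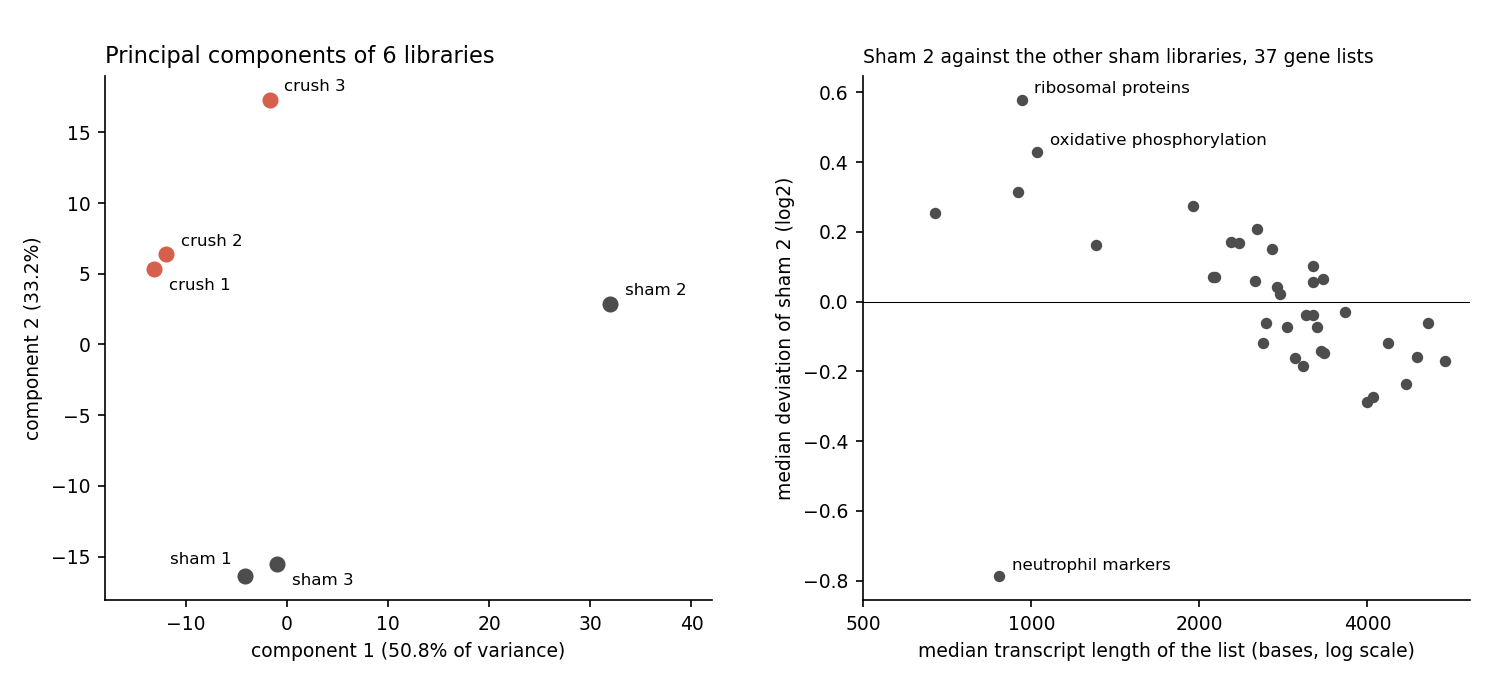
Left, the sham (grey) and crush (red) libraries along the first principal components of log2(FPKM + 1), which hold 50.8% and 33.2% of the variance, with sham 2 apart at 31.9 on the horizontal one. Right, the median log2 deviation of sham 2 from the other sham libraries for each of 37 lists (points) against the list's median transcript length in bases (log axis), highest for the ribosomal list at 0.58.

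Single isoforms were compared next, each by its own FPKM. Of 24485 isoforms tested, 15 passed, 13 higher and 2 lower after crush, from 12 genes. Of the 15, 8 were assembled from the reads without a reference identifier and 6 belonged to genes that did not pass. On the log2(FPKM + 1) scale the largest rises were in Npy, whose isoforms TCONS_00110722 and TCONS_00106227 rose from 9.85 ± 2.68 to 103 ± 16.0 and from 5.98 ± 0.945 to 54.7 ± 10.4 FPKM (log2 changes 3.27 and 2.99, adjusted p = 0.0251 for both). The Car3 isoform TCONS_00084418 rose from 3.57 ± 0.475 to 28.6 ± 5.83 FPKM (2.68). TCONS_00075534 of Usp20, a deubiquitinating enzyme, was listed at 0 in all sham libraries and at 8.67, 5.35 and 4.89 FPKM in crush 1 to 3 (adjusted p = 0.0299). TCONS_00035512 of Auh, a mitochondrial enzyme of leucine breakdown that also binds RNA, stood at 0.00103, 0.0706 and 0.00358 FPKM in sham 1 to 3. In crush 1 to 3 it stood at 7.11, 4.31 and 6.47 FPKM (adjusted p = 0.0251). Its first exon is listed at 3 bases, as is that of TCONS_00033181, another Auh isoform, which did not pass (12.7 ± 8.79 and 1.93 ± 2.55 FPKM). Auh as a whole did not pass in limma either (adjusted p = 0.219). With so little sequence of its own, the value of TCONS_00035512 rests largely on how shared reads were divided. Both isoforms that fell came from Afg3l2, a mitochondrial protease. TCONS_00060652 stood at 4.10, 4.29 and 4.36 FPKM in sham 1 to 3 (adjusted p = 0.0241) and TCONS_00060651 at 3.28, 2.22 and 2.77 FPKM (adjusted p = 0.0422). Both were listed at 0 in every crush library. Afg3l2 as a whole did not pass in limma (log2 change 0.06, adjusted p = 0.791). Its other tested isoforms had higher means in crush (11.3 to 14.5 and 7.13 to 12.2 FPKM) but did not pass. Only 1 exon of TCONS_00060652, of 112 bases, lies outside exons of the other isoforms. Its value rests largely on how shared reads were divided. In limma 0 isoforms passed without sham 1, sham 3, crush 1 or crush 3 (2096, 1758, 1566 and 1677 at an unadjusted p under 0.05), 3 without crush 2 and 45 without sham 2. The count was 7 with no filter on low values, 30 and 42 with upper-quartile and quantile scaling, 1355 with sample weights and 34 among isoforms of good quantification status.

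A further test asked whether the isoforms of a gene changed by different amounts. Of 6746 genes, 30 passed (limma diffSplice), 2 of which had also passed as whole genes. Of the 9 other splits of the 6 libraries into 3 and 3, 3 called more genes (78, 55 and 42). In Bcat1, a cytosolic aminotransferase of branched-chain amino acids on the minus strand of chromosome 6, isoform TCONS_00109044, whose first exon spans 145024409 to 145024734 (mm9), stood at 3.85 ± 0.780 in sham and 13.3 ± 2.94 FPKM in crush, or 10.2% and 30.2% of the gene's total. TCONS_00107522, whose first exon lies downstream at 144997083 to 144997349, stood at 21.1 ± 1.70 and 16.2 ± 1.102 FPKM, or 55.9% and 36.8%. The difference passed (adjusted p = 0.00233), while the gene as a whole did not (log2 change 0.21, adjusted p = 0.222) and neither did TCONS_00109044 alone (adjusted p = 0.0840). The smallest adjusted p values belonged to Afg3l2 (4.50e-06), Laptm4a, a lysosomal membrane protein (4.50e-06), and Klhl5, a Kelch-domain protein (3.87e-05), followed by Bcat1 and Auh (0.00630). In Laptm4a an isoform listed at 0 in every sham library stood at 1.99, 2.33 and 2.86 FPKM in crush 1 to 3, about 1.23% of the gene's total. Neither this isoform alone nor the gene as a whole passed in limma (adjusted p = 0.0534 and 0.389). The isoform's first exon overlaps that of TCONS_00027276, another isoform of the gene. In Klhl5 the isoform TCONS_00102543 went from 1.01% to 11.3% of the total, but neither it alone nor the gene passed in limma (adjusted p = 0.158 and 0.148). Here a gene's total is that of its tested isoforms. The first exon of TCONS_00102543 is listed at 9 bases, and its other exons lie within exons of other isoforms of the gene. Its share therefore rests largely on how shared reads were divided. Exons of Afg3l2 shared 48.9% of their bases with Tubb6, which rose, on the opposite strand. In simulated data with known changes and independent noise, 24.6% of the genes this test called had no isoform difference. It called 17, 70, 23, 13, 9 and 20 genes without sham 1, 2 and 3 and crush 1, 2 and 3, 103 with no filter on low values and 4 at a mean of at least 5 FPKM.

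**Figure D5:**
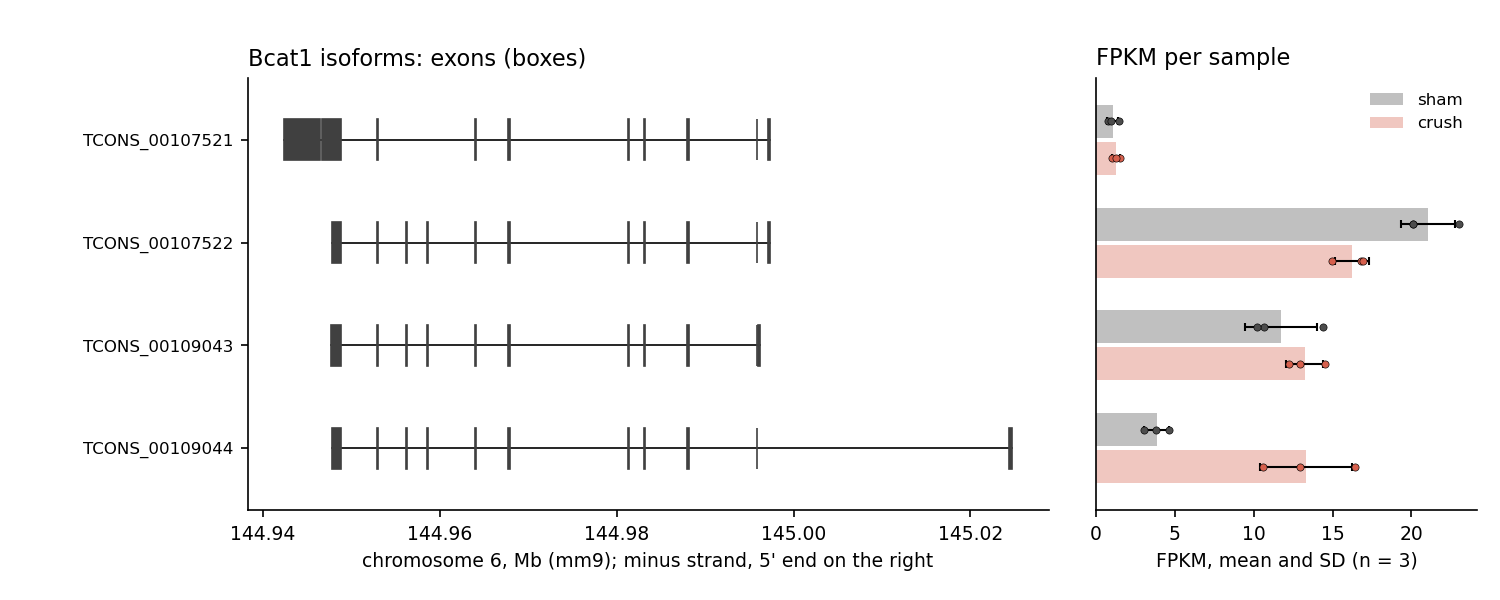
Left, exons (boxes) of the 4 Bcat1 isoforms tested, along chromosome 6 in megabases (mm9; minus strand, so the 5' end is on the right). Right, the FPKM of each isoform in every sham (grey) and crush (red) library as points, with bars for means and lines for the SD (n = 3): TCONS_00109044, with the outermost first exon, has means of 3.85 and 13.3 FPKM.

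The authors' deposited table holds their own test of each isoform between the groups. It calls 3858 of the 25544 isoforms whose test ran, 2111 higher and 1747 lower after crush, and 1200 of the calls have no finite fold change; for 27416 isoforms its test failed. The authors' group estimate failed for 27085 isoforms in crush and 2712 in sham. It exceeded 10 times the highest single library, taken as at least 1 FPKM, for 200 isoforms in crush and 105 in sham. Among these 200 crush estimates, 181 were failed ones. Folds drawn from such estimates are uncertain, and the failed tests leave the count of the authors' calls uncertain. In the authors' deposited table Sprr1a goes from 87.4 to 587 FPKM (log2 change 2.75), while the tests of every Atf3 and Npy isoform failed. The 2 Gal isoforms of the authors' deposited table go from 28.1 to 132 and from 25.4 to 112 FPKM (2.23 and 2.14). Its 2 most abundant Gap43 isoforms go from 127 to 317 and from 88.1 to 120.1 FPKM (1.32 and 0.45), and its most abundant Pvalb isoform from 113 to 48.7 FPKM (-1.22). Of the 3858 calls in the authors' deposited table, 1382 were of isoforms tested here. Of the 15 isoforms called here, 5 were called there too, all 5 with the same sign, and the authors' test had failed for the other 10. Both tests used the same libraries, so this overlap is not independent support.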

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

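The restriction to good quantification status, the omission of both sham 2 and crush 3, the removal of the length trend and, for lists, quantile scaling were chosen only after seeing the data. The 464 genes became 295 at a mean of at least 5 FPKM, where fewer genes were tested. From reference isoforms only, with 8465 genes tested, they became 67. They became 1429 with sample weights (0.162 for sham 2) and 866 at adjusted p under 0.1, a looser threshold. The count was 1610 without both sham 2 and crush 3 (462 of them among the 464) and 965 with the length trend removed (446 among the 464). Leaving out 1 library gave 53 (without crush 1) to 1174 genes (without sham 2), the latter including all 464. The 15 isoforms became 7 without a filter, 30 and 42 with upper-quartile and quantile scaling, 1355 with sample weights, 94 at adjusted p under 0.1 and 34 of status OK, and 0 to 45 without 1 library (0 without sham 1, sham 3, crush 1 or crush 3, with limma and 1566 to 2096 at an unadjusted p under 0.05; 45 without sham 2). The 30 genes with differing isoforms became 103 without a filter, 4 at a mean of at least 5 FPKM and 9 (without crush 2) to 70 (without sham 2) without 1 library. Of the 21 lists, 0 passed camera with an estimated correlation (7 at an unadjusted p under 0.05) and 7 passed fry. The ribosomal list, which did not pass, ran from 0.000266 (upwards, without sham 2) to 0.901 (without crush 1) in adjusted p, and turned upwards also without both sham 2 and crush 3 (0.0123). Syt4 went from 0.45 to -0.031 (log2 change) from reference isoforms only. Except where named, the cause was not tested. Apart from the replicate block below, counts stayed within 1.5 times the reported ones under the other alternatives. The authors' calls were 2602 at q under 0.01. DESeq2, planned only for counts, was not run, because the table holds none; the unknown depth keeps the spread of low genes from being set beside counting error.

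With the replicate number as a block, 50 genes, 0 isoforms (limma, 1560 at an unadjusted p under 0.05), 5 genes with differing isoforms and 20 lists passed; the call of the cholesterol list was lost (adjusted p = 0.0513). Deviations from the group means correlated across genes at 0.37, -0.31 and -0.49 for numbers 1, 2 and 3, and sham 2 went best with crush 3 (0.59). Not every sample thus correlated best with its own number. Whether equal numbers mark samples handled together cannot be told from this. Sham 2 and crush 3 shared a falling trend with transcript length (Spearman rho -0.58 and -0.48), which could hide a pairing.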

Other observations

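Among 38 RNA splicing regulators 2 rose, 0 fell and 36 did not pass (5 rising when adjusted over the list alone; median 0.09): the neuronal splicing activator Srrm4 rose from 3.45 ± 0.496 to 5.40 ± 0.245 FPKM (SD, n = 3; log2 change 0.53, adjusted p = 0.0374) and the RNA-binding protein Khdrbs2 by 0.37 (0.10 from reference isoforms alone). Of 16 immediate early genes, the antiproliferative gene Btg2 rose (0.59) and the phosphatase Dusp5 fell (-0.48), and 14 did not pass (2 rising and 1 falling when adjusted over the list alone; median 0.27). In the unfolded protein and integrated stress response, 1 of 29 rose, the glutathione-degrading enzyme Chac1 (0.61), 0 fell and 28 did not pass (1 rising when adjusted over the list alone; median 0.09). In cholesterol biosynthesis, 1 of 21 rose, the sterol reductase Hsd17b7, from 10.6 ± 2.61 to 21.9 ± 2.32 FPKM (1.01), 0 fell and 20 did not pass (1 rising when adjusted over the list alone; median 0.06). In glycolysis the glucose transporter Slc2a1 rose (0.48), the aldolase Aldoc fell (-0.52), and 15 of 17 did not pass (1 rising and 3 falling when adjusted over the list alone; median -0.05). In limma 0 of 13 small RNA pathway, 0 of 25 interferon and class I, 0 of 10 cell cycle and 0 of 4 red blood cell genes passed, also when adjusted over the list alone (medians 0.05, 0.14, -0.02 and 0.19). Their members of smallest adjusted p were Dgcr8 (0.315), Stat2 (0.208), Mcm6 (0.136) and the globin Beta-s (0.791); the cell cycle mean (0.07) and camera's direction were upwards.

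Camera called the splicing (adjusted p = 0.00638), immediate early (0.00638), unfolded protein (0.0240) and cholesterol lists (0.0494) higher and did not call the glycolysis (0.384), small RNA (0.667), interferon (0.380), cell cycle (0.667) or red blood cell lists (0.573). The adjusted p = 0.341, 0.542, 0.583, 0.624, 0.871, 0.871, 0.871, 0.871 and 0.871 with an estimated correlation, in that order. The splicing call was lost without sham 2 (0.140; range over alternatives 0.000968 to 0.341), the immediate early call without sham 1 (0.0525; range 0.00120 to 0.542), the unfolded protein call without sham 1 (0.146), sham 3 (0.118) or crush 3 (0.0585; range 0.000579 to 0.583), and the cholesterol call without sham 3 (0.294) or crush 3 (0.292; range 0.00576 to 0.624). The interferon list passed without crush 2 (0.00637; range 0.00637 to 0.958) and the red blood cell list without crush 1 (0.0178; range 0.0178 to 0.991).

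Of the tests that follow, those of depth and of the length trend as the whole cause of the position of sham 2 were chosen only after the result was seen. Sham 2 stood apart from sham 1 and sham 3. Its deviation from them fell with transcript length over genes (Spearman rho -0.58), which may reflect RNA quality or library preparation. Each library was set against the others of its group, so the rho of sham 1 (0.55) and sham 3 (0.47) partly mirrors sham 2. These 2 values are not independent comparisons. In crush 3, set against the other crush libraries, rho was -0.48. The length trend does not account for all of it, since with the trend removed the root mean square deviation of sham 2 was still 0.302 (0.359 before). It was 0.195 and 0.173 in sham 1 and sham 3, each measured against a mean that includes sham 2. Lower depth is argued against by the width of the deposited intervals, 1.01 times that of the other sham libraries. Cells of another type cannot be told apart as a part of it, since the highest median deviation of a non-neuronal list, of red blood cells, was only 0.25 and the neutrophil list lay at -0.79.

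Macrophage markers rose after crush, with a median log2 change of 0.83. More non-neuronal tissue captured with the neurons could have raised them. Markers of the other types did not move alike. The medians were -0.0088 in satellite glia and 0.02 in endothelium, which argue against a like rise of all non-neuronal tissue. They were 0.18 in Schwann cells and 0.31 in fibroblasts, where all 16 members were higher. More captured tissue of those kinds, with macrophages in it, is therefore not excluded. Sham 2 did not set the rise, as the median without it was 0.85. More macrophages near the neurons after crush, or more of these transcripts in each cell, stay open too and were not tested.

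Markers of myelinated low-threshold and proprioceptive neurons were lower after crush (median log2 change -0.44, 95% of 20 members lower). Fewer such neurons among those captured may account for this, or lower expression in each neuron, and the 2 cannot be told apart: the members ranged from -1.59 to 0.30, and the number and size of the captured neurons were not given in the sources used here.

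The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 464 genes and the highest other 0 (limma, with 2158 and at most 1189 at an unadjusted p under 0.05), and 15 isoforms against 5 and 21 lists against 19, so that 1 split, the real one, gave as many in each. For genes with differing isoforms 4 splits gave at least the real 30, and the highest was 78 for sham 1, sham 3 and crush 1 against sham 2, crush 2 and crush 3. That count points to a structure of the samples, and its cause was not tested.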
